A study of Mus musculus with 18 samples.

How the data were processed

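The sources used here were the sample labels, the submitters' processing notes and the deposited tables. One lysate was made per dish, a small aliquot of it was taken for total RNA, and both kinds of library were made with the ARTseq kit, per the labels. Reads were aligned by the authors to mouse build GRCm38, and the aligner, the counting program and the annotation release are not given in the sources used here. The count values, a table of all libraries with a row per transcript, are whole-number read counts without normalization as deposited by the authors. The signal values of the deposited comparison tables, in the column baseMean, are means of normalized counts made by the authors. The log2 values of those tables, log2FoldChange and its error lfcSE, are estimates by the authors as deposited. The score values, in the column stat, are the authors' test statistics as deposited. The p-value columns, pvalue and padj, are the authors' test results as deposited, raw and adjusted. These columns have the layout of DESeq2 results, but the tool is not stated per the file headers.

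The count table had 27382 transcript rows, of which 6378 were 0 in all libraries and 8528 shared their counts with another row. Rows with equal counts or 1 Ensembl gene were merged to 15307 features. Where a feature held different counts, which happened for 62, the row with most reads was kept, and 16 features were shared by genes of different symbol. Gene symbols came from the authors' tables and named 9787 features. Features without a symbol held between 1.8 and 2.1% of reads per library and stayed in the fits under the name of their transcript. The authors' tables had 12372 rows, 102 of them without a symbol, and in the rapamycin table of translational efficiency 26 symbols had been turned into dates. Genes were marked as uncertain when their counts stayed close to those of another gene in all 18 libraries and the symbols met a rule. The rule asked that both symbols begin alike or that 1 have a form common for predicted genes or copies. It marked Rps27 and Rps27rt, but also pairs such as Aprt and Fbxw8, so a mark need not mean a related gene.

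Genes entered a fit when they passed filterByExpr of edgeR with a minimum count of 10 and a minimum total of 15. This left 11271 genes for RNA, 11281 for footprints and 10988 for translational efficiency. Library sizes were scaled with TMM factors. Counts were fitted with the quasi-likelihood method of edgeR (glmQLFit with robust dispersion, glmQLFTest), separately for the 9 RNA and the 9 footprint libraries. Translational efficiency was the interaction of assay and treatment in a fit of all 18 libraries, that is the log2 change of footprints minus that of RNA. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors were derived from the fold change and its F statistic. The biological coefficient of variation was 5.72% in RNA, 6.38% in footprints and 6.05% in the joint fit. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and Python with pandas 2.3.3 and matplotlib 3.10.9.

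The 21 gene lists were written from general knowledge before the data were examined. They cover cytosolic ribosomal proteins, translation factors and other known TOP mRNAs, ribosome biogenesis and MYC-regulated nucleolar genes, eIF4E-sensitive mRNAs, cell cycle, glycolysis and HIF targets, sterol and fatty acid synthesis, ATF4 targets and amino acid supply, and nuclear-encoded oxidative phosphorylation. They also cover mitochondrial ribosomal proteins, mitochondrially encoded genes, lysosome and autophagy, mTOR pathway and cap-binding components, immediate early and ERK feedback genes, FoxO targets, chaperones and heat shock, neural progenitor and glial markers, and granule neuron lineage and neuronal markers. The last 3 hold markers of oligodendrocytes, of microglia and blood cells, and of endothelial cells, pericytes and fibroblasts. Lists were tested as sets with camera of limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, whose p is the one printed. These p-values were adjusted by the Benjamini-Hochberg method over the lists tested in a comparison. A set call counts as lost when it passed at the preset and not at the estimated correlation.

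Genes were named by a rule fixed with the lists. For footprints and efficiency it took the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM (counts scaled to library size) of at least 4 and no overlap between groups, and for RNA the 5 largest of each. It added up to 4 members of each list with the smallest p, and always Mycn, Myc, Ccnd1, Odc1, Eef2, Eef1a1, Mtor, Eif4ebp1, Atf4 and Larp1. No row carried the name Myc, so it was not analysed here. Some genes that the rule selects are withheld from the text.

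The fits were repeated with DESeq2 size factors, TMM factors without the ribosomal protein and TOP lists, no filter on low counts beyond 1 count, the Wald test of DESeq2, a fit of only the treatments compared, a replicate block, and a fit without each replicate in turn. Added after the values were seen were library totals without TMM and removal of a lowess trend (span 0.5) of fold change on genomic span, available for 9469 RNA and 9449 footprint genes, 96.8% of those with a symbol. Treatment groups were also regrouped in all 10 splits of 3 against 3. Unchanged groups sharing their controls were simulated 20 times, drawn around the mean of the observed DMSO libraries. Power was examined on counts drawn anew from the fitted model, with 200 genes changed in the Rapalink-1 libraries, or for efficiency in its footprint libraries only. Standard errors of list medians used 2000 bootstrap draws of genes, which are not independent replicates.

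Whether replicates are independent cultures is not stated. The p-values measure only the spread between these samples, which may be technical. Pairs of replicates differed by 1.94 to 9.5 times the variance of counting alone.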

Results

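Ribosome footprints, the stretches of mRNA shielded from nuclease by translating ribosomes, and total RNA were sequenced from mouse medulloblastoma cells of the GTML line. These cells come from tumours of mice that express a human MYCN transgene in progenitors of the hindbrain. The cells received DMSO, 50 nM Rapalink-1 or 5 nM rapamycin for 3 h, with 3 replicates per treatment, which gave 18 libraries, 9 per assay. Rapamycin is an allosteric inhibitor of the growth kinase mTOR, and Rapalink-1 joins rapamycin to an inhibitor of the kinase's ATP site. After transcripts of each gene were collapsed, the footprint libraries held 14150068, 7692625 and 10371672 reads for DMSO, 11023142, 7794216 and 8193342 for Rapalink-1, and 12820072, 11608873 and 13069883 for rapamycin. The RNA libraries held 10781667, 11210853 and 6788365 reads for DMSO, 13300292, 12149285 and 11887026 for Rapalink-1, and 9397100, 12073278 and 9471322 for rapamycin. No spike-in is recorded, so each change below is relative to the other genes of the same library. Values are log2 fold changes ± standard error from fits with 3 replicates per group. P-values of genes are adjusted over all genes tested, and those of gene lists over the lists tested in a comparison. Genes named for the size of their change had no overlap between the 3 values of each treatment.

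Positions refer to the mouse build GRCm38. Mycn lies on chromosome 12 from 12936093 to 12941836, and Odc1 on chromosome 12 from 17544808 to 17551502. Ccnd1 lies on chromosome 7 from 144929931 to 144939831, Eef2 on chromosome 10 from 81176631 to 81182509, and Eef1a1 on chromosome 9 from 78478453 to 78481724. Mtor lies on chromosome 4 from 148448582 to 148557685, Eif4ebp1 on chromosome 8 from 27260327 to 27275656, Atf4 on chromosome 15 from 80255184 to 80257545, and Larp1 on chromosome 11 from 57973418 to 58062034. Each interval spans a protein-coding gene. The row for mouse Mycn may hold reads of the human transgene, and their share was not determined.

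The comparison of Rapalink-1 with DMSO addresses which mRNAs change in translation when mTOR is blocked toward both the S6 kinases and the eIF4E-binding proteins. Translation of the protein synthesis machinery fell most. Translational efficiency, the change of footprints beyond that of RNA, fell for all 78 cytosolic ribosomal protein genes tested, with a median of -2.30 (adjusted p = 4e-07 with an estimated correlation). It also fell for all 22 translation factors and other mRNAs known to start with a 5′ terminal oligopyrimidine tract (TOP), with a median of -1.70 (adjusted p = 6.4e-08 with an estimated correlation). Under library totals without TMM these medians were -1.93 and -1.33, with 78 and 21 members lower. Eef2, the elongation factor that moves the ribosome along mRNA, fell by 4.23 ± 0.06 (adjusted p = 1.4e-49). Eef1a1, which delivers aminoacyl-tRNA, fell by 4.13 ± 0.054 (adjusted p = 2.9e-51).

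Among ribosomal proteins, Rps2 stood at -3.71 ± 0.33, Rps18 at -3.18 ± 0.067 and Rps7 at -2.99 ± 0.066, all past the test. Rps27 fell by 3.27 ± 0.071, but its reads are shared with the near-identical Rps27rt. In the TOP list, Tpt1, a small protein tied to growth, fell by 3.39 ± 0.07, and Eef1b2 fell by 2.97 ± 0.067. Eef2 had 4180 ± 160 footprint CPM (counts scaled to library size) with DMSO and 394 ± 2.1 with Rapalink-1 (SD, n = 3), while its RNA went from 2910 ± 120 to 5320 ± 83 CPM. The ribosomal protein list took 9 ± 0.28% of footprint reads with DMSO and 2.58 ± 0.01% with Rapalink-1 (SD, n = 3).

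Single mRNAs outside these lists also lost efficiency, Odc1, several chaperones and Eif4ebp1 among them. Odc1, the rate-limiting enzyme of polyamine synthesis and a MYC target, fell in efficiency by 2.59 ± 0.067 (adjusted p = 1.8e-37). Its footprints went from 420 ± 5.4 to 73.1 ± 3.4 CPM, against 980 ± 16 and 1060 ± 29 for its RNA (SD, n = 3). Of 20 chaperone genes, 12 fell and 1 rose, with a median of -0.37 (adjusted p = 0.043 with an estimated correlation) that became 0.00 under library totals, with 8 lower and 6 higher. Among them, Hspa8 fell by 2.36 ± 0.057, Hsp90ab1 by 1.78 ± 0.061 and Cct2, a subunit of the folding chamber for actin and tubulin, by 1.57 ± 0.066. Eif4ebp1, which encodes a repressor of the cap-binding protein eIF4E, fell by 1.29 ± 0.11 (adjusted p = 1.4e-14). Of the 22 genes of the mTOR pathway and cap binding, 6 rose and 6 fell, with a median of 0.11 and a mean of -0.02 (adjusted p = 0.75 with an estimated correlation). Eif4g2 rose by 0.57 ± 0.075 and Rps6kb1, an S6 kinase, by 0.72 ± 0.11. Larp1, which binds TOP mRNAs, stood at 0.12 ± 0.084 (adjusted p = 0.24), but passed the test under library totals at 0.49 (adjusted p = 2.7e-06).

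Among 12 mRNAs described as sensitive to eIF4E, 4 rose and 4 fell in efficiency, with a median of -0.08 (adjusted p = 0.33 with an estimated correlation), or 0.29 under library totals. Besides Odc1, the apoptosis inhibitor Mcl1 fell by 0.81 ± 0.094 and the cyclin Ccnd3 by 0.67 ± 0.14, while Hif1a rose by 0.55 ± 0.077. The cyclin Ccnd1 fell by 0.67 ± 0.17 (adjusted p = 0.00092), but stood at -0.30 under library totals (adjusted p = 0.12). The row of mouse Mycn rose by 0.30 ± 0.065 (adjusted p = 0.00015). Its footprints went from 742 ± 34 to 898 ± 9.7 CPM and its RNA from 793 ± 16 to 802 ± 37 (SD, n = 3). The kinase gene Mtor stood at -0.27 ± 0.11 (adjusted p = 0.048), a call that was lost without DMSO replicate 2 or 3 or any Rapalink-1 replicate (adjusted p from 0.059 to 0.13). It was also lost with a replicate block (adjusted p = 0.051) and with the DESeq2 Wald test (adjusted p = 0.06), and the value was 0.10 under library totals.

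Metabolic groups moved less, and their direction under library totals is given with each. Of 53 nuclear genes of oxidative phosphorylation, 39 fell and 3 rose, with a median of -0.35 (adjusted p = 0.039 with an estimated correlation) that became 0.02, with 17 lower and 13 higher. Of 65 mitochondrial ribosomal proteins, 34 fell and 1 rose, with a median of -0.27 (set call lost, adjusted p = 0.16 with an estimated correlation) that became 0.10, with 9 lower and 20 higher. Of 16 glycolytic and HIF target genes, 10 fell and 0 rose, with a median of -0.30 (adjusted p = 0.026 with an estimated correlation) that became 0.07, with 5 lower and 4 higher. Examples are the ATP synthase subunit Atp5c1 at -1.09 ± 0.065, Mrps24 at -1.17 ± 0.11, Gpi1 at -1.26 ± 0.071, Aldoa at -1.08 ± 0.069 and Ldha at -0.95 ± 0.061. Of 28 ATF4 targets and amino acid supply genes, 10 fell and 2 rose, with a median of -0.12 (set call lost, adjusted p = 0.36 with an estimated correlation) that became 0.25, with 6 lower and 13 higher. Within this list, Mthfd2 of folate metabolism fell by 1.38 ± 0.078 and Phgdh of serine synthesis by 1.16 ± 0.072. Of 25 sterol and fatty acid genes, 13 fell and 3 rose, with a median of -0.21 (adjusted p = 0.43 with an estimated correlation) that became 0.16, with 5 lower and 11 higher. Of 30 ribosome biogenesis genes, 14 fell and 5 rose, with a median of -0.19 (adjusted p = 0.44 with an estimated correlation) that became 0.18, with 3 lower and 14 higher, and the nucleolar helicase Ddx21 fell by 0.89 ± 0.074.

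Several groups held risers. Of the 13 genes encoded by mitochondrial DNA, 11 rose in efficiency, with a median of 1.95 (adjusted p = 0.44 with an estimated correlation) and 2.32 under library totals. The RNA set call of these genes was lost (adjusted p = 0.62 with an estimated correlation), at a list median of -0.91. RNA fell for 4 of them. Of these calls, mt-Nd4l and mt-Nd2 were lost with no count filter (adjusted p = 0.053 and 0.055), with a replicate block (0.086 and 0.094), with only the treatments compared (0.096 and 0.1), and without DMSO replicate 1 or any Rapalink-1 replicate (from 0.052 to 0.12). The mt-Nd4l call was also lost without DMSO replicate 3 (adjusted p = 0.066). Footprints rose for 3, or 0 adjusted over the list alone, with a median of 1.02, and for all 13 under library totals, at 1.29. The complex I subunit mt-Nd5 rose in efficiency by 2.32 ± 0.45 and mt-Nd6 by 1.83 ± 0.37. These genes took 0.321, 0.548 and 0.814% of footprint reads in the DMSO libraries and 1.01, 1.36 and 1.81% in the Rapalink-1 libraries. Within both treatments this share rose with the replicate number, for a reason that was not determined. Of 10 granule neuron and neuronal markers, 6 rose and 1 fell, with a median of 0.42 (adjusted p = 0.2 with an estimated correlation), or 0.79 with 8 higher under library totals. Ptch1, the hedgehog receptor, rose by 1.06 ± 0.16 and Zic2 by 0.64 ± 0.1. Of 27 cell cycle genes, 9 rose and 9 fell, with a median of -0.02 (adjusted p = 0.94 with an estimated correlation) and 0.35 under library totals. Mki67, a proliferation marker, rose by 0.68 ± 0.089, and Rrm2, a subunit of ribonucleotide reductase, fell by 0.72 ± 0.073. Of 26 lysosome and autophagy genes, 6 rose and 7 fell (adjusted p = 0.85 with an estimated correlation). Of 13 immediate early genes and of 12 FoxO targets, 5 rose and 0 fell each, both with a median of 0.26 (adjusted p = 0.44 each with an estimated correlation). Of 8 neural progenitor and glial markers 1 rose, Slc1a3 by 0.39 ± 0.14 (set test adjusted p = 0.91 with an estimated correlation). Markers of other cells were sparse: 1 of 11 oligodendrocyte genes, 2 of 14 microglial and blood genes and 1 of 14 vascular and fibroblast genes could be tested. Their values were -0.62 ± 0.2 for Cnp, -1.53 ± 0.23 for Itgam, 1.06 ± 0.36 for Hbb-bs and -0.42 ± 0.099 for Acta2, all past the test. With DMSO the vascular and fibroblast list took 0.0277% of footprint reads but 0.00361% of RNA reads. The source of this gap was not determined, which limits the value of Acta2 as a marker. Adjusted over the list alone, the higher and lower counts in efficiency became 2 and 14 for chaperones, 6 and 15 for ribosome biogenesis, 3 and 10 for glycolysis, 12 and 0 for mitochondrial DNA genes, and 2 and 36 for mitochondrial ribosomal proteins; the 78 and 22 falls above stayed.

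In all, efficiency rose for 2455 and fell for 2182 of 10988 genes, and 215 and 404 of these changes reached a log2 fold change of 1. Under library totals, which shift the median of all genes by 0.367, 5552 rose and 841 fell. Library totals move all genes of a comparison together, so a list can change sign under them without changing its place among the other genes. In 49.5% of genes the 3 values of each treatment did not overlap, against 10% by chance.

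**Figure D1:**
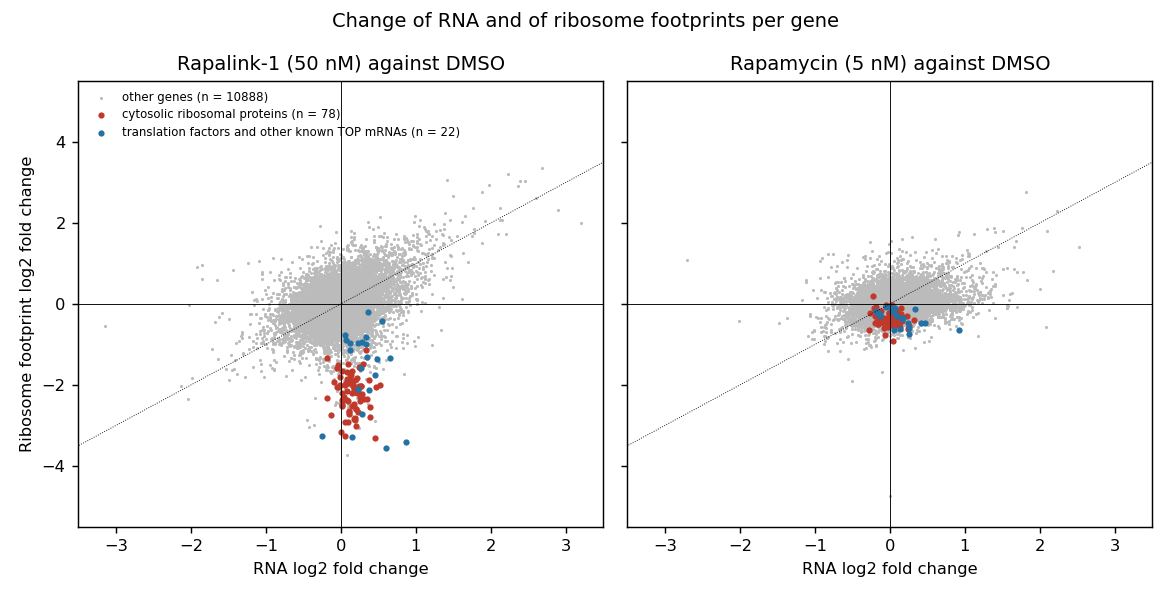
Each point is a gene, with the log2 fold change of RNA on the x axis and of footprints on the y axis, for Rapalink-1 (50 nM) and rapamycin (5 nM) against DMSO; the dotted line marks equal change, red points are 78 ribosomal protein genes, blue points 22 other TOP mRNAs and grey points the rest of 10988 genes, with 1 point outside the axes. With Rapalink-1 the red and blue points lie far below the line, at median efficiency changes of -2.30 and -1.70, and with rapamycin nearer to it, at -0.38 and -0.43.

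Footprints alone showed the same leading groups with Rapalink-1. All 78 ribosomal protein genes fell, with a median of -2.16 (adjusted p = 0.0005 with an estimated correlation), and all 22 TOP mRNAs fell, with a median of -1.32 (adjusted p = 0.00022 with an estimated correlation). Eef1a1 fell by 3.56 ± 0.046, Eef2 by 3.41 ± 0.05, Tpt1 by 3.29 ± 0.053, the poly(A)-binding protein gene Pabpc1 by 3.25 ± 0.056 and Rpl27a by 3.16 ± 0.059. The largest rises were in Klhl24 at 3.35 ± 0.082, the transcriptional repressor Hbp1 at 3.04 ± 0.086, the ubiquitin ligase gene Fbxo32 at 3.04 ± 0.11 and Txnip, an inhibitor of glucose uptake, at 2.91 ± 0.11. Fbxo32 and Txnip belong to the FoxO targets, of which 8 of 12 rose and 0 fell, with a median of 0.65 (adjusted p = 0.017 with an estimated correlation). Further rises were Tcp11l2 at 2.38 ± 0.12, Coq8a at 2.37 ± 0.14, Fbxl20 at 2.24 ± 0.13 and the clock gene Nr1d2 at 2.07 ± 0.079.

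Footprints of lipid and folding genes fell as well. Of 25 sterol and fatty acid genes 23 fell, with a median of -0.56 (adjusted p = 0.043 with an estimated correlation), among them Msmo1 by 1.64 ± 0.064. Footprints of 16 of 20 chaperones, 56 of 65 mitochondrial ribosomal proteins and 19 of 28 ATF4 targets fell, with medians of -0.58, -0.41 and -0.30; these set calls were lost at adjusted p = 0.076, 0.076 and 0.06 with an estimated correlation. Under library totals these medians were -0.31, -0.14 and -0.03, with 12, 30 and 12 members lower and 3, 7 and 9 higher. Footprints of 44 of 53 oxidative phosphorylation genes and 13 of 16 glycolytic genes fell, with medians of -0.36 and -0.38 (adjusted p = 0.043 and 0.032 with an estimated correlation), or -0.09 and -0.11 under library totals, with 25 and 8 lower and 11 and 1 higher. Immediate early genes had 9 of 13 higher at a median of 0.61, and granule neuron markers 7 of 10 at 0.48, calls lost at adjusted p = 0.097 and 0.06 with an estimated correlation. Adjusted over the list alone, 17 chaperones, 20 ATF4 targets, 58 mitochondrial ribosomal proteins and 14 glycolytic genes fell. Ccnd1 fell by 1.25 ± 0.11 (adjusted p = 3e-12), and Pdcd4, an inhibitor of the helicase eIF4A, rose by 1.37 ± 0.067. Footprints rose for 2896 and fell for 3161 of 11281 genes, or 5399 and 1590 under library totals, which shift the median by 0.272; 58.7% of genes had no overlap, against 10% by chance.

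In RNA, most TOP mRNAs and FoxO targets rose with Rapalink-1, and most sterol genes fell. RNA of 19 of 22 TOP mRNAs rose, with a median of 0.31 (adjusted p = 0.0042 with an estimated correlation), led by Eef2 at 0.87 ± 0.038, Eif4b at 0.66 ± 0.04 and Eef1a1 at 0.61 ± 0.035; under library totals the median was 0.17 with 12 higher. RNA of 48 of 79 ribosomal protein genes rose, with a median of 0.15 and a set call that was lost (adjusted p = 0.19 with an estimated correlation), Rpl3 at 0.46 ± 0.037 among them; under library totals it was 0.01, with 18 higher and 14 lower. Of 12 FoxO targets 8 rose and 1 fell, with a median of 0.54 (adjusted p = 0.0068 with an estimated correlation), including the cyclin-like Ccng2 at 2.89 ± 0.12, Fbxo32 at 2.39 ± 0.17, Txnip at 2.36 ± 0.12 and the insulin signalling adaptor Irs2 at 0.93 ± 0.084. The protocadherin Pcdh8 rose by 3.20 ± 0.15, Klhl24 by 2.68 ± 0.073 and Hbp1 by 2.46 ± 0.083. RNA of 20 of 25 sterol and fatty acid genes fell and 1 rose, with a median of -0.34 (adjusted p = 0.0042 with an estimated correlation); Msmo1 fell by 1.45 ± 0.058, Sqle by 0.82 ± 0.052, Hmgcs1 by 0.78 ± 0.05 and Scd2 by 0.73 ± 0.046.

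Cell cycle RNAs rose for 16 and fell for 3 of 27 genes, with a median of 0.17 (adjusted p = 0.02 with an estimated correlation) that became 0.03 under library totals, where 7 rose and 7 fell. The replication licensing genes Cdt1 at 0.90 ± 0.058, Mcm7 at 0.59 ± 0.046 and Mcm6 at 0.51 ± 0.042 led. Lysosome and autophagy RNAs rose for 15 and fell for 2 of 26, with a median of 0.20 (adjusted p = 0.044 with an estimated correlation) that became 0.06 under library totals, with 5 in each direction. Flcn, a regulator of mTOR at the lysosome, rose by 0.85 ± 0.071 and its partner Fnip1 by 0.57 ± 0.07. Immediate early and ERK feedback RNAs rose for 7 of 13 and fell for 1, with a median of 0.34 (adjusted p = 0.048 with an estimated correlation), the phosphatase gene Dusp6 at 0.77 ± 0.12 and Junb at 0.60 ± 0.086 among them. Atf4, a regulator of amino acid supply, fell by 0.90 ± 0.046, and its target Trib3 fell by 2.13 ± 0.26, while the list had 7 higher and 10 lower of 28 (adjusted p = 0.62 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 fell by 0.82 ± 0.04, in a list with 8 higher and 9 lower of 20. Mitochondrial ribosomal protein RNAs fell for 22 and rose for 6 of 65, at a median of -0.09 (adjusted p = 0.05 with an estimated correlation). Glycolytic RNAs rose for 5 and fell for 4 of 16, with a median of 0.01 and a mean of -0.10, and oxidative phosphorylation RNAs rose for 12 and fell for 9 of 53, with a median of -0.04 and a mean of 0.00. Adjusted over the list alone, 48 ribosomal protein RNAs and 19 TOP mRNAs rose, as did 17 cell cycle and 9 FoxO target RNAs, and 21 sterol RNAs fell. RNA of Mycn stood at 0.02 ± 0.041 (adjusted p = 0.8), but was called lower under library totals, at -0.12 (adjusted p = 0.015). RNA rose for 2182 and fell for 2123 of 11271 genes, or 1123 and 3732 under library totals, which shift the median by -0.137; 46.1% had no overlap, against 10% by chance.

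The comparison of rapamycin with DMSO addresses the part of the response that an allosteric inhibitor reaches at 5 nM. The same machinery fell by less. Efficiency fell for 64 of 78 ribosomal protein genes, with a median of -0.38 (adjusted p = 0.02 with an estimated correlation), and for 15 of 22 TOP mRNAs, with a median of -0.43 (adjusted p = 9.1e-05 with an estimated correlation). Tpt1 fell by 1.01 ± 0.068, Rpl17 by 0.94 ± 0.074, Eef2 by 0.88 ± 0.057 (adjusted p = 6.4e-17), Rps3a1 by 0.86 ± 0.065, Eef1b2 by 0.85 ± 0.065 and Eef1a1 by 0.75 ± 0.052. Odc1 fell by 0.24 ± 0.063 (adjusted p = 0.0061). Values short of the test were 0.16 ± 0.1 for Eif4ebp1 (adjusted p = 0.31), -0.07 ± 0.16 for Ccnd1 (adjusted p = 0.83), 0.10 ± 0.065 for Mycn (adjusted p = 0.32) and -0.23 ± 0.11 for Mtor (adjusted p = 0.15).

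In RNA the rapamycin libraries stood apart from both other groups in how expression followed genomic span, and in footprints the libraries of both drugs departed from DMSO in opposite directions. Across genes, which are not independent replicates, the change against DMSO followed genomic span with a Spearman correlation of 0.26 in RNA, -0.17 in footprints and -0.34 in efficiency; for Rapalink-1 these were -0.01, 0.21 and 0.21. Per footprint library the correlation was -0.38 to -0.24 for rapamycin, 0.23 to 0.26 for Rapalink-1 and -0.19 to 0.01 for DMSO. The 3 rapamycin footprint libraries also carry another form of name than the other 6. In the numbers that end the library names, all rapamycin libraries, RNA included, come after all DMSO and Rapalink-1 libraries. What these numbers stand for is not stated. Gene groups that moved along with this trend include oxidative phosphorylation, where 18 of 53 genes rose in efficiency and 1 fell, with a median of 0.16 (adjusted p = 0.037 with an estimated correlation); with the span trend removed the median was 0.05, with 11 higher and 2 lower. Cox8a rose by 0.63 ± 0.093, Sdhd by 0.59 ± 0.086 and Atp5g1 by 0.46 ± 0.074. Mitochondrial ribosomal proteins rose for 11 of 65, with a median of 0.08 (set call lost, adjusted p = 0.32 with an estimated correlation) that turned to -0.03 with the trend removed. The falls in ribosomal proteins and TOP mRNAs were larger with the trend removed, at medians of -0.56 and -0.47, with 71 and 17 lower.

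The largest single falls in efficiency were Pabpc1 at -1.55 ± 0.21, the RNA polymerase II subunit Polr2a at -1.23 ± 0.21, Ankrd52 at -1.22 ± 0.14, Ylpm1 at -1.22 ± 0.13, the splicing protein gene Srrm2 at -1.20 ± 0.12, Qser1 at -1.19 ± 0.13, Gm340 at -1.17 ± 0.18 and Baz2a at -1.12 ± 0.14. The largest rises were the histone gene Hist1h2ba at 1.65 ± 0.18, Gm12728 at 1.54 ± 0.29, Mycl, a relative of Mycn, at 1.23 ± 0.16, Emc6 at 1.03 ± 0.14, Gpr27 at 1.00 ± 0.21, Eid2 at 0.97 ± 0.19, Jund at 0.91 ± 0.092 and Nudt19 at 0.89 ± 0.17. Of the mTOR pathway genes 2 rose and 7 fell in efficiency, with a median of -0.11 (adjusted p = 0.39 with an estimated correlation). Larp1 stood at -0.28 ± 0.083 (adjusted p = 0.012), a call lost without DMSO replicate 1 (adjusted p = 0.063), without rapamycin replicate 1 (adjusted p = 0.12) and with the span trend removed, at -0.16 (adjusted p = 0.2). Immediate early genes had 2 of 13 higher, with a set call that was lost (adjusted p = 0.32 with an estimated correlation). The other lists had no set call: 1 higher and 5 lower of 30 for ribosome biogenesis, 2 lower of 12 for eIF4E-sensitive mRNAs, 3 higher and 1 lower of 27 for the cell cycle, 3 and 5 of 25 for sterol genes, 2 and 2 of 28 for ATF4 targets, 1 and 3 of 20 for chaperones, and none of the 13 mitochondrial DNA genes. Adjusted over the list alone, 68 ribosomal protein genes and 17 TOP mRNAs fell, and 25 oxidative phosphorylation genes rose and 2 fell. Efficiency rose for 716 and fell for 1082 of 10988 genes, or 930 and 846 under library totals; 31% had no overlap, against 10% by chance.

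**Figure D2:**
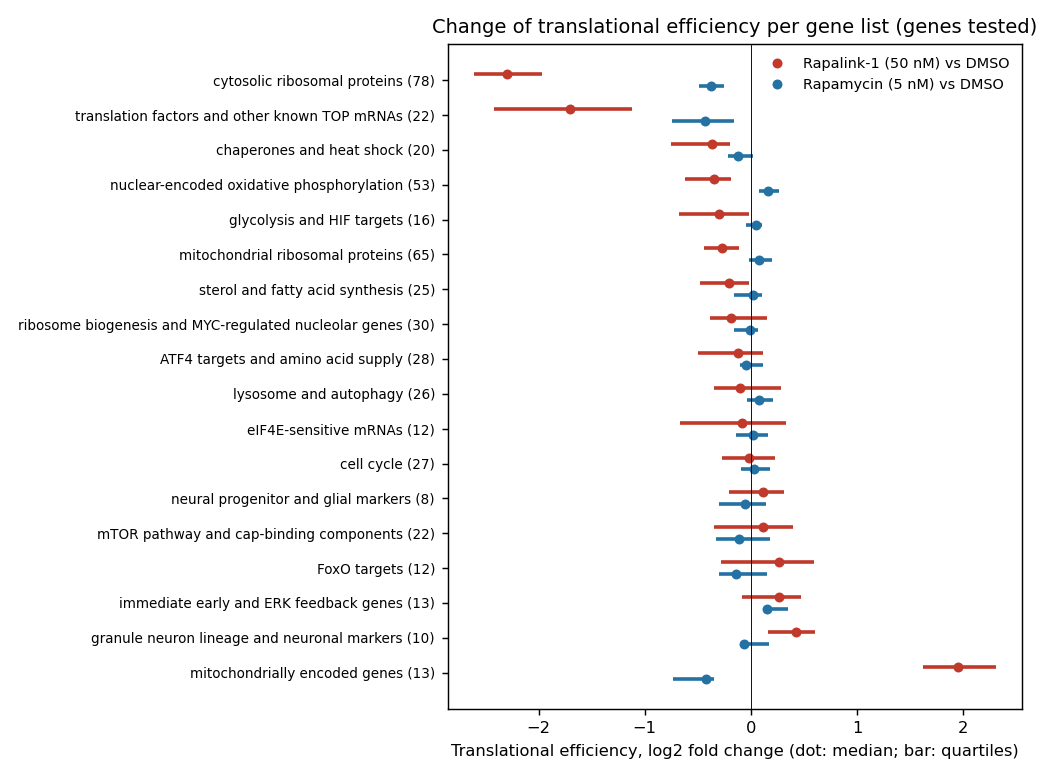
For each of 18 gene lists, the dot is the median and the bar the quartile range of the log2 fold change in translational efficiency against DMSO (x axis), red for Rapalink-1 (50 nM) and blue for rapamycin (5 nM), with the number of genes tested in parentheses. Ribosomal proteins and TOP mRNAs lie lowest with Rapalink-1, and TOP mRNAs (-0.43), mitochondrial DNA genes (-0.42) and ribosomal proteins (-0.38) with rapamycin; under library totals the Rapalink-1 medians of the metabolic lists turn from below 0 to 0 or above, as for oxidative phosphorylation (-0.35 to 0.02), and with the span trend removed the rapamycin median of mitochondrial ribosomal proteins turns from 0.08 to -0.03.

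In footprints, rapamycin lowered the machinery, sterol synthesis and amino acid supply. Footprints of 69 of 78 ribosomal protein genes and 18 of 22 TOP mRNAs fell, with medians of -0.40 and -0.31 (adjusted p = 0.017 and 0.0036 with an estimated correlation). Footprints of 18 of 25 sterol genes fell, with a median of -0.36 (adjusted p = 0.017 with an estimated correlation), Hmgcs1 by 0.82 ± 0.05 among them. Footprints of 15 of 30 ribosome biogenesis genes fell and 1 rose, at a median of -0.14 (adjusted p = 0.027 with an estimated correlation), and 13 of 28 ATF4 targets fell, at -0.17 (adjusted p = 0.035 with an estimated correlation). FoxO targets rose for 7 of 12, with a median of 0.46 (adjusted p = 0.0077 with an estimated correlation). Klhl24 rose by 2.29 ± 0.085, Fbxl20 by 1.87 ± 0.13, Hbp1 by 1.86 ± 0.09, Ubald2 by 1.73 ± 0.091 and Fbxo32 by 1.41 ± 0.13. Hspa8 fell by 0.99 ± 0.045, the glycolytic regulator Pfkfb3 by 0.95 ± 0.084, Ifrd1 by 0.95 ± 0.066 and Rps24 by 0.77 ± 0.049. The falls of 13 of 20 chaperones, at a median of -0.18, had a set call that was lost (adjusted p = 0.13 with an estimated correlation). The counts of falls adjusted over the list alone were 71 ribosomal protein genes, 19 TOP mRNAs, 18 sterol genes and 17 ATF4 targets. Footprints rose for 987 and fell for 1060 of 11281 genes, or 1391 and 654 under library totals; 31.4% had no overlap, against 10% by chance.

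In RNA, rapamycin lowered sterol synthesis and raised FoxO targets. RNA of 19 of 25 sterol genes fell, with a median of -0.26 (adjusted p = 0.0056 with an estimated correlation); Msmo1 fell by 1.01 ± 0.057, Sc5d by 0.84 ± 0.099, Nsdhl by 0.75 ± 0.096, Hmgcs1 by 0.58 ± 0.05 and Insig1, a sterol sensor, by 0.56 ± 0.048. RNA of 7 of 12 FoxO targets rose, with a median of 0.38 (adjusted p = 0.017 with an estimated correlation), Ccng2 by 2.10 ± 0.13, Fbxo32 by 1.66 ± 0.18 and Irs2 by 0.79 ± 0.086. Klhl24 rose by 2.23 ± 0.075, from 17.9 ± 1.1 CPM with DMSO to 83.5 ± 1.4 (SD, n = 3). Pdcd4 rose by 1.08 ± 0.069 and Deptor, an inhibitor bound to mTOR, by 1.07 ± 0.18. Hspa8 fell by 0.88 ± 0.037, Atf4 by 0.73 ± 0.046 and Mycn by 0.21 ± 0.042. Mitochondrial ribosomal protein RNAs fell for 18 of 65, at a median of -0.07 (adjusted p = 0.029 with an estimated correlation). RNA of TOP mRNAs rose for 10 and fell for 4 of 22, at a median of 0.09 (adjusted p = 0.083 with an estimated correlation), and of ribosomal proteins for 12 and 15 of 79, at -0.01. With p adjusted over the list alone, 19 sterol and 19 mitochondrial ribosomal protein RNAs fell and 9 FoxO target RNAs rose. RNA rose for 1532 and fell for 1180 of 11271 genes; 35.6% had no overlap, against 10% by chance.

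The direct comparison of Rapalink-1 with rapamycin tests the difference between both drugs, at doses of 50 and 5 nM that differ. Across genes, the difference followed genomic span with a Spearman correlation of 0.38 in efficiency, 0.31 in footprints and -0.2 in RNA. With the span trend removed, 79.2, 84.3 and 89.6% of these calls stayed, among genes with a span. Values below keep the trend unless stated. Separate handling of the rapamycin libraries cannot be told apart from the difference between the drugs. Efficiency was lower with Rapalink-1 for all 78 ribosomal protein genes, with a median difference of -1.89 (adjusted p = 4.7e-06 with an estimated correlation), and for 21 of 22 TOP mRNAs, with a median of -1.28 (adjusted p = 1.9e-06 with an estimated correlation). Eef1a1 differed by -3.38 (95% interval -3.48 to -3.27) and Eef2 by -3.35 (-3.47 to -3.23). Odc1 differed by -2.36 (-2.49 to -2.22), Hspa8 by -2.25 ± 0.057 and Eif4ebp1 by -1.45 (-1.67 to -1.23). Mcl1 was lower by 1.00 ± 0.093. Ccnd1 differed by -0.60 (-0.93 to -0.27), but by -0.41 without Rapalink-1 replicate 3 (adjusted p = 0.06) and by -0.28 under library totals (adjusted p = 0.16). Mycn differed by 0.20 (0.07 to 0.33), a call lost without Rapalink-1 replicate 1 or 2 or rapamycin replicate 1 (adjusted p = 0.059, 0.05 and 0.056). No difference was detected for Mtor, at -0.04 (-0.25 to 0.18), or for Atf4, at -0.21 (-0.40 to -0.01), whose adjusted p was 0.073. The Mtor value was 0.29 under library totals (adjusted p = 0.022) and -0.35 with the span trend removed (adjusted p = 0.005), and the Atf4 value passed the test without Rapalink-1 replicate 2, at -0.27 (adjusted p = 0.047).

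Oxidative phosphorylation genes were lower in efficiency with Rapalink-1 for 45 and higher for 1 of 53, with a median difference of -0.54 (adjusted p = 0.0044 with an estimated correlation), or -0.22 under library totals. Mitochondrial ribosomal proteins were lower for 46 and higher for 1 of 65, with a median of -0.37 (adjusted p = 0.046 with an estimated correlation), or -0.05 under library totals. Glycolytic genes were lower for 10 and higher for 1 of 16, with a median of -0.37 (adjusted p = 0.021 with an estimated correlation), or -0.05 under library totals. All 13 mitochondrial DNA genes were higher, with a median of 2.36 (adjusted p = 0.42 with an estimated correlation), mt-Cytb at 2.97 ± 0.56 and mt-Nd6 at 2.21 ± 0.37 among them. The call of mt-Nd4l was lost without Rapalink-1 replicate 2 or 3 (adjusted p = 0.07 and 0.076) and without rapamycin replicate 2 or 3 (0.1 and 0.051). Chaperones were lower for 13 and higher for 2 of 20, a set call that was lost (adjusted p = 0.098 with an estimated correlation). Adjusted over the list alone, the lower counts were 78 for ribosomal proteins, 21 for TOP mRNAs, 45 for oxidative phosphorylation and 47 for mitochondrial ribosomal proteins. Mki67 was higher by 1.46 ± 0.088, the autophagy kinase gene Ulk1 by 1.45 ± 0.22, Ptch1 by 1.13 ± 0.15 and the mTOR partner Rptor by 1.09 ± 0.11; the lysosomal Lamp1 was lower by 1.21 ± 0.07. In footprints Ccnd1 differed by -1.05 (-1.27 to -0.82), Odc1 by -2.45 (-2.56 to -2.33) and Txnip by 2.28 ± 0.098. In RNA Pcdh8 was higher by 2.21 ± 0.13, Txnip by 1.87 ± 0.12 and the linker histone Hist1h1d by 1.16 ± 0.038, while Ankrd52 was lower by 1.94 ± 0.13, the acetyltransferase gene Ep300 by 1.53 ± 0.13 and the helicase gene Ddx6 by 1.49 ± 0.065. Odc1 RNA differed by -0.06 (-0.13 to 0.02), but passed the test at -0.20 under library totals (adjusted p = 4.4e-05) and at -0.10 with the span trend removed (adjusted p = 0.022). Efficiency was higher with Rapalink-1 for 2873 and lower for 2631 of 10988 genes, or 5174 and 1196 under library totals, which shift the median by 0.325. Footprints were higher for 2870 and lower for 3119 of 11281, or 4974 and 1831 with a shift of 0.221, and RNA for 2213 and 2422 of 11271, or 1056 and 3962 with a shift of -0.142. The shares without overlap were 57.2, 59.5 and 52.2%, against 10% by chance.

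**Figure D3:**
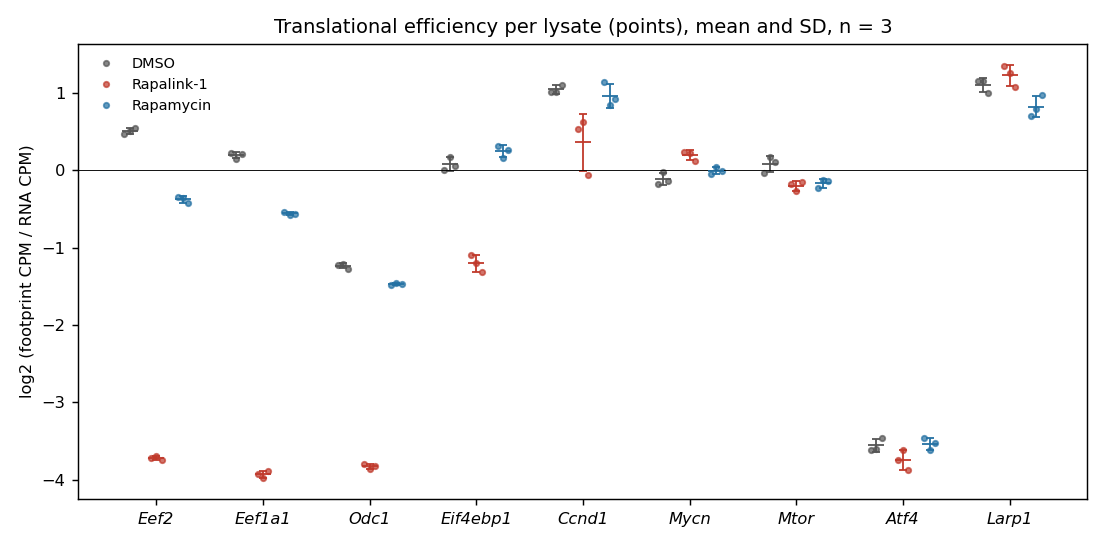
Log2 ratio of footprint to RNA CPM (y axis) for Eef2, Eef1a1, Odc1, Eif4ebp1, Ccnd1, Mycn, Mtor, Atf4 and Larp1 in each lysate (points), with mean ± SD (n = 3), by treatment on the x axis. The mean of Eef2 went from 0.51 ± 0.04 with DMSO to -3.72 ± 0.03 with Rapalink-1 and -0.37 ± 0.04 with rapamycin, and that of Odc1 from -1.23 ± 0.04 to -3.83 ± 0.03 and -1.47 ± 0.01.

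Genes called with both drugs against DMSO overlapped mostly in the same direction in RNA and footprints, and in similar numbers in the same and in opposite directions in efficiency. In footprints 531 genes were higher and 632 lower with both drugs, and 283 were called in opposite directions, against 253, 297 and 549 for independent lists, with 0 same-direction calls in simulated unchanged groups, which by design yield hardly any calls and so set no bound. Klhl24, Hbp1, Fbxo32 and Fbxl20 were among the shared rises and Hspa8 and Tpt1 among the shared falls. In RNA 569 were higher and 529 lower with both, with 361 opposite, against 297, 222 and 517 for independent lists and 0 same-direction calls in simulation. In efficiency 171 were higher and 335 lower with both, with 536 opposite, against 160, 215 and 384 for independent lists and 0 same-direction calls in simulation. Efficiency changes followed genomic span in opposite directions, at 0.21 for Rapalink-1 and -0.34 for rapamycin. These overlaps keep that trend, so its share in the opposite calls was not determined. The share of all genes with the same sign was 60.4% in RNA, 60% in footprints and 51.4% in efficiency, against 50.5, 50.6 and 50.9% in simulation. The covariance of fold changes between both drugs was 0.0475 in RNA, 0.0756 in footprints and 0.0268 in efficiency, against 0.000654, 0.000919 and 0.00113 in simulation, and the correlations across genes were 0.381, 0.416 and 0.124 against 0.04, 0.05 and 0.039. The 3 DMSO replicates cannot be split into groups of 2 or more, so part of the excess may come from the shared controls. Simulated groups were drawn around the mean of the same DMSO libraries, which leaves out the error of the shared controls. The simulated values therefore set no baseline for it. How much of the observed covariance, correlation and same-sign share comes from the shared controls was not determined.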

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

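Counts of calls stayed within 1.5 times the reported count in each of the 9 comparisons and under each alternative. Leaving out 1 replicate at a time gave 3665 to 4280 genes for Rapalink-1 against DMSO in RNA, 5489 to 5685 in footprints and 4006 to 4333 in efficiency. For rapamycin against DMSO the ranges were 1992 to 2764, 1512 to 2029 and 1246 to 1924, and for Rapalink-1 against rapamycin 3901 to 4097, 5376 to 5564 and 4866 to 5026. The other alternatives gave 3807 to 4855, 5611 to 6989 and 4299 to 6393 genes for Rapalink-1 against DMSO. They gave 2339 to 2748, 1804 to 2405 and 1428 to 1958 for rapamycin against DMSO, and 4142 to 5085, 5400 to 6805 and 4777 to 6370 for the direct comparison. The authors' deposited tables held 4524 same-direction calls in efficiency for Rapalink-1 and 1758 for rapamycin, with 0 opposite.

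Library totals without TMM and removal of the span trend were chosen after seeing the data. Library totals shift all genes of a comparison together, by up to 0.367 in efficiency with Rapalink-1, so values of the other sign and smaller than the shift turn by construction, and their place among other genes stays. Under library totals, values of called genes turned sign for Odc1 RNA with Rapalink-1 (-0.03), for Larp1 and Mtor footprints with Rapalink-1 (0.00 and 0.01), and for Larp1 footprints in the direct comparison (0.06). The same happened for Mtor efficiency with Rapalink-1 (0.10). Values short of the test turned and passed it at -0.12 for Mycn RNA with Rapalink-1 (adjusted p = 0.015) and at 0.29 for Mtor efficiency in the direct comparison (adjusted p = 0.022). Medians of lists with a set call turned in 8 cases, to 0.00 for cell cycle RNA in the direct comparison, 0.06 for ribosome biogenesis footprints with Rapalink-1, and 0.10 for eIF4E-sensitive footprints in the direct comparison. In efficiency with Rapalink-1 they turned to 0.07 for glycolysis, 0.25 for ATF4 targets, 0.02 for oxidative phosphorylation, 0.10 for mitochondrial ribosomal proteins and 0.00 for chaperones. Set calls counted here and below are those at the preset correlation, and some were lost with an estimated one. Lost calls include cell cycle RNA in the direct comparison (adjusted p = 0.076 with an estimated correlation). In efficiency they include ATF4 targets and mitochondrial ribosomal proteins with Rapalink-1, and mitochondrial ribosomal proteins with rapamycin. Medians of lists without a set call turned in 24 further cases, among them efficiency with Rapalink-1 for sterol genes (0.16), ribosome biogenesis (0.18), lysosome (0.27), eIF4E-sensitive mRNAs (0.29) and cell cycle (0.35). With the span trend removed, 13 medians of lists without a set call turned, and those of 2 with such a call turned to 0.02 for eIF4E-sensitive footprints in the direct comparison and to -0.03 for mitochondrial ribosomal protein efficiency with rapamycin. For the span trend the cause was not tested.

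Among the other gene values, 2855 kept their side of the threshold, 69 fell short of it and 15 passed it. Called values among the 2855 also kept direction, while values short of the threshold in both fits may have changed sign. Among the other list results, 1017 stayed on their side of the threshold or, for medians, within their spread, though some of these medians are among the changes of sign counted above. A further 48 fell short, 38 passed and 12 medians moved by more than their spread, some of them past 0. Pairing of replicates by number was examined, since the numbers might name a shared day. Residuals of libraries with the same number correlated at -0.06 to 0.02 in RNA and -0.05 to 0.07 in footprints, and at -0.03 to 0.04 between footprints and RNA, with 0 of 9 pairs over 0.1 in each set. These correlations run over all genes and can miss a pattern in a few. The share of footprint reads from mitochondrial DNA genes rose with replicate number for DMSO and for Rapalink-1, but not for rapamycin (0.396, 0.405 and 0.373%). A replicate block gave 4142, 2479 and 4467 calls in RNA, 6138, 2166 and 6076 in footprints and 4638, 1794 and 5498 in efficiency, in the order of the comparisons above. A block by lysate gave 4642, 1825 and 5478 in efficiency. An alternative on normalized values was not run, because the table holds counts.

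Recovery of changes was simulated at the depth and replicate number of the data, and neither was varied. Of simulated log2 changes of 0.5, the fits recovered 70.6% in RNA, 60.9% in footprints and 45.7% in efficiency, and of changes of 1 they recovered 92.4, 83.1 and 76.3%. False calls made up 6.5, 4.8 and 6.5% of all calls in simulation. These counts were drawn from the fitted model itself with only 200 genes changed, while far more genes were called in the data. The rates therefore need not hold for the fits of the data.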

Other observations

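Histone genes were not on a list, and this set was chosen after the data were seen. Replication-dependent histone mRNAs lack a poly(A) tail and are made in S phase with the DNA they package. With Rapalink-1, RNA of 56 of 63 rose and 0 fell, with a median of 0.59, and with rapamycin 36 fell and 0 rose, with a median of -0.13. Many of these genes are near-identical copies whose reads cannot be separated; summed over copies, rapamycin lowered RNA of H2B (-0.23 ± 0.031) and H3 (-0.12 ± 0.035), while H1 (-0.08 ± 0.032), H2A (-0.12 ± 0.092) and H4 (0.09 ± 0.089) fell short of the test. Their efficiency moved the opposite way, with 41 lower and 1 higher for Rapalink-1 at a median of -0.45, and 41 higher and 0 lower for rapamycin at 0.50. Between both drugs, RNA was higher with Rapalink-1 for 58, at a median of 0.61, and efficiency lower for 56, at -0.86. Footprints rose for 21 and fell for 6 with Rapalink-1, at 0.11, and rose for 24 and fell for 0 with rapamycin, at 0.31; these counts too include copies that share reads. Summed over copies, footprints with rapamycin passed the test for H1 (0.36 ± 0.095) and H3 (0.47 ± 0.082) but not for H2A, H2B and H4, and with Rapalink-1 for H1 (0.62 ± 0.096), H2B (0.31 ± 0.082) and H3 (0.29 ± 0.081) but not for H2A (-0.25 ± 0.12) and H4 (-0.02 ± 0.13). Under library totals the efficiency median for Rapalink-1 was -0.08, with 20 higher and 12 lower, against 0.54 for rapamycin and -0.53 between both drugs. Efficiency changes also followed genomic span, at -0.34 for rapamycin and 0.21 for Rapalink-1. The trend could not be removed for histones because no span was available for them.

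All tests here were chosen after the histone rise was seen, and those of S phase and normalization after their own values were seen. Summed over gene copies, RNA rose by 0.90 ± 0.032 in H1 (5 genes), 0.80 ± 0.035 in H3 (12), 0.65 ± 0.09 in H4 (13), 0.48 ± 0.093 in H2A (18) and 0.22 ± 0.031 in H2B (15), so even the lowest class, 0.22, argued against an uneven split of reads between copies. The lowest median over 4 normalizations was 0.45, under library totals. These scalings move all genes together, by -0.137 for library totals against TMM, so a median of 0.59 had to stay above 0. This test therefore says nothing on normalization as a source of the rise. All 4 are relative scalings without a spike-in, so they cannot show whether histone RNA rose in absolute amount. More cells in S phase was tested in a first form, which asked whether S-phase genes of the cell cycle list rise about as much as histones; their median of 0.18 against 0.59 counted against it. That test was replaced after its result was seen, because histone mRNAs may respond more steeply, and in the second form the lowest median over 4 normalizations was 0.04 with a standard error of 0.086, so more cells in S phase remains a possible explanation.

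The test of proportion and its bound were chosen after the result was seen, and the test of normalization before. RNA of the ribosomal protein and TOP lists, 101 genes, rose with Rapalink-1 at a median of 0.18 ± 0.021 (bootstrap standard error), while footprints fell. Over 4 normalizations the lowest median was 0.04, under library totals, where the median of all genes was -0.135. Normalization therefore leaves open whether these RNAs rose in absolute amount. Library totals move all genes together, so the place of these RNAs above other genes could not change under them. Across 100 of these genes the correlation of RNA and footprint changes was 0.07 (95% interval -0.13 to 0.26) against 0.34 across all genes, and with rapamycin -0.27 (-0.44 to -0.08) against 0.26. The intervals and the bootstrap standard error treat genes as independent replicates, which they are not, so both are too narrow. A footprint change contains the RNA change, which pushes the correlation upward, so an RNA rise in proportion to the loss of footprints stays open.

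The test of library handling was written after the rapamycin RNA libraries were seen to stand apart, and the share that stayed was chosen as the measure for the tests of genomic span after their values were seen. Rapamycin RNA differed from both other groups in the same direction in 1354 of 2712 called genes, and Rapalink-1 RNA in 2785 genes. The rapamycin RNA libraries correlated with span at 0.21, 0.21 and 0.24, against -0.19 to -0.05 for the other 6. After removal of the trend, 81.3% of the RNA calls stayed (2043 of 2513), which argued against the span trend as the source of most of them, while in efficiency 67% stayed (1111 of 1658), which leaves the trend open there. Counting calls gained as well, 98.6% as many RNA and 86.1% as many efficiency calls were made after removal. Of the DMSO footprint libraries, 0 carry the name form of the rapamycin libraries, so separate preparation or sequencing of the rapamycin libraries cannot be told apart from the drug.

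Splits of the 6 libraries of each comparison were run as planned. In each of the 9 comparisons 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05, since the smallest is 0.1. The real splits gave 4305, 2712 and 4635 genes in RNA, 6057, 2047 and 5989 in footprints and 4637, 1798 and 5504 in efficiency, for Rapalink-1 and rapamycin against DMSO and for the direct comparison. The highest other split gave 1 gene for rapamycin against DMSO in footprints and in efficiency and 0 in the other comparisons.

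Among 3428 features with at least 5000 footprint reads, 34 had more than 8 times as many footprint as RNA reads, against a median ratio of 1.12, thresholds chosen after the values were seen. Fkbp1a had 26250 footprint and 1814 RNA reads, and Zmiz1 9155 and 468. The mitochondrial share of RNA reads was 1.73, 1.45 and 2.27% with DMSO, 1.4, 1.46 and 1.43% with Rapalink-1 and 1.67, 1.92 and 1.71% with rapamycin.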
